A study of Mus musculus with 8 samples.

How the data were processed

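The series holds single-cell RNA sequencing (10x Chromium, 5-prime gene expression) of cells from 2 gut-draining immune tissues of mice, the mesenteric lymph nodes (MLN) and the Peyer's patches (PP). Germ-free female C57BL/6 mice were gavaged at 6 weeks of age with 1 of 4 microbiotas and were killed 4 weeks later, at 10 weeks of age. The microbiotas were a mock community (MC), MC with Allobaculum sp. 128, MC with Akkermansia muciniphila, and MC with both species. Per the labels, cells of 3 mice per microbiota were pooled before library preparation, which leaves 1 library per microbiota and tissue and 8 libraries in all.

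The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, made by the authors with Cell Ranger on genome build mm10. The submitters' processing notes give Cell Ranger 5.0 and Seurat 3.2.1, and the matrix headers give Cell Ranger 4.0.0. The annotation release and the filter that chose the barcodes are not given in the sources used here. Each matrix lists 31053 genes. Coordinates were looked up by gene identifier in GENCODE M21 (mm10, counted from 1), and 238 of the 238 named genes matched. The sex-linked transcripts went against the label in 0 of 8 libraries, and 0 of 28 pairs of libraries held the same totals for every gene.

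Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet (run through Scanpy 1.11.5) scored doublets. Its own threshold did not separate the scores in most libraries, so the highest scores were removed at an assumed rate of 0.008 per 1000 barcodes in the library. Of 49446 barcodes, 1982 failed these limits and 2493 were called doublets, from 3.50% to 8.24% per library, which left 44971 cells. Counts were scaled per cell, reduced to 2000 variable genes and 30 principal components, and clustered with Leiden at resolution 1 on 15 neighbours (leidenalg 0.10.2, igraph 0.11.9), with all libraries together and without integration. V, D and J genes were kept out of the variable genes. Clusters were named from marker lists fixed in advance, and every class name ends in "-like" because no protein was measured. An activated B cluster that met no marker rule stayed unnamed. The plan counted all B lineage cells but plasma cells as B-like, and leaving out this unnamed cluster is a departure from it. A fit with the cluster included was run as an alternative.

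The MC microbiota was the control throughout. For the microbiota comparisons each group has 1 library per tissue, so no test was run and no count of changed genes is given. Shares of cells carry exact Clopper-Pearson 95% intervals, and ratios of shares carry Katz intervals. UMIs were summed per library and class and scaled to the class total (CPM). Ratios of CPM carry exact conditional binomial 95% intervals. These intervals cover counting error only, and neither differences between mice nor between library preparations enter them. Those of gene levels also treat each UMI as independent, so they are too narrow where a few cells hold many of the UMIs. A count of 0 was taken to allow up to 3 counts. Departure from additivity was the log2 ratio of MC with both species to MC, minus the sum of the log2 ratios of the single additions. Gene lists, 24 in all, were fixed before the data were examined, as were the classes, tests, naming rule and most of the alternatives. They cover the germinal centre, naive B, class switch, plasma cell secretory, MHC class II, follicular helper T, Th17, Th1, Th2, regulatory T and naive T programs. Others cover gut homing, type I interferon, interferon gamma, proliferation, immediate early genes, heat shock, mitochondrially encoded genes, oxidative phosphorylation and glycolysis. The last ones hold markers of epithelial, erythroid, macrophage or neutrophil, and stromal cells. A list is described by the median log2 ratio of its detected members, with a pseudocount of 1 UMI, and by the percentile of that median among 10000 random lists. In a random list each gene was replaced by one of the 100 genes nearest in expression.

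For the tissue comparison the 4 pools are the replicates. By the study's design the MLN and PP libraries of a microbiota come from the same mice, so the pool was a block. Deviations from the tissue means correlated between the libraries of a pool at -0.315 to 0.180 over the tested classes. They were below 0 for MC+both in every class. Each class with at least 20 cells in every library was tested, and the plasma cell-like class was left out because 1 MLN library held 18 such cells. UMI totals per library and class went through filterByExpr, TMM scaling and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01 and again with an estimated correlation. Shares were compared by the mean paired difference and an exact two-sided sign-flip permutation test, whose smallest possible p with 4 pairs is 0.125. In simulated data with 200 changed genes, edgeR recovered 92.9% of genes changed by 1 log2 unit in the B-like class and 60.8% in the CD8 T-like class. The count and share intervals covered the simulated value in 94.7% to 96.0% of runs. These runs drew independent counts, so they do not test UMIs gathered in a few cells.

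Named genes followed a fixed rule. For the microbiota comparisons, genes needed at least 50 UMIs over both libraries in each tissue, the same direction in MLN and PP and intervals that exclude no change in both. They were ranked by the smaller of the 2 log2 ratios, and the 6 highest and 6 lowest were taken for each comparison with MC and 4 each way for MC with both against each single addition. For the tissue comparison, genes needed an adjusted p under 0.05, a mean logCPM of at least 5 and the same sign in all 4 pools. The 10 largest changes each way were taken in the CD4 T-like class and in B-like cells outside germinal centres, and 5 each way elsewhere. Antigen receptor segments, mitochondrial, ribosomal protein and haemoglobin genes and unnamed models were not named, and 11 CD4 and 12 B cell genes were always named. List members and V genes named beside these were chosen as examples after their values were seen.

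Alternatives covered doublets kept, stricter quality limits, Leiden resolutions of 0.6 and 1.5, clustering each tissue apart, and marker genes after thinning cells to 1000 UMIs. For gene levels they also covered TMM factors, totals without immunoglobulin, mitochondrial and ribosomal protein genes, and pseudocounts. For the tissue comparison they covered DESeq2 1.42.0, no filter on low counts, no block, and leaving out each pool in turn. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.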

Results

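The data are UMI counts from 8 pooled libraries, 4 microbiotas in each of the MLN and the PP, with 1 library per microbiota and tissue and no replicate of a microbiota within a tissue. The libraries held 11589593 (MC MLN), 22679657 (MC PP), 13245635 (MC+Allobaculum MLN), 11907963 (MC+Allobaculum PP), 11740472 (MC+A.muciniphila MLN), 12464159 (MC+A.muciniphila PP), 15219578 (MC+both MLN) and 10223366 (MC+both PP) UMIs. Between 3965 and 8519 cells per library were kept, with a median of 1330 to 2192 UMIs per cell. The MC PP library had 9.92% of its barcodes outside the quality limits, against 2.59% to 6.42% in the other PP libraries.

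The first question, from the series title, is how each added species and both together went with the make-up of the immune cells. Germinal centre B-like cells, in which B cells mutate and select their receptors, made up more of the B lineage in MLN with each single addition than with MC alone, which for A. muciniphila depended on how mixed barcodes are counted. They were 4.59% of the B lineage with MC (95% interval 3.80 to 5.49), 6.16% with MC+Allobaculum (5.29 to 7.13), 7.82% with MC+A.muciniphila (6.66 to 9.11) and 5.57% with MC+both (4.62 to 6.65). The log2 ratio to MC was 0.42 (0.09 to 0.76) for Allobaculum, 0.77 (0.43 to 1.11) for A. muciniphila and 0.28 (-0.09 to 0.64) for both. With barcodes of mixed T and B transcripts in the denominator the ratio for A. muciniphila was 0.14 (-0.20 to 0.48), an interval that includes 0. In PP the same share lay between 12.3% and 14.3%, with log2 ratios to MC of 0.01, 0.22 and 0.19. The PP ratios for A. muciniphila and for both turned to -0.06 and -0.12 under the stricter quality limits.

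Follicular helper T-like cells, which help germinal centre B cells, were 6.10% of CD4 T-like cells in MLN with MC, 10.0% with Allobaculum, 9.31% with A. muciniphila and 8.54% with both. In PP they were 35.5%, 35.3%, 47.8% and 44.7%. The share of CD4 T-like cells with a Bcl6 UMI after thinning gave smaller MLN log2 ratios to MC, of 0.05 for Allobaculum and 0.18 for A. muciniphila, where the clusters gave 0.71 and 0.61. With mixed barcodes in the denominator the MLN ratio for A. muciniphila turned to -0.40. In PP the ratio of both to MC, 0.33, turned to -0.0731 at a Leiden resolution of 0.6 and to -0.0834 with thinned Bcl6, and was 0.0289 with the tissues clustered apart. Bcl6 is also expressed in B cells, so its share in them, 7.60% to 12.2%, is no measure of free RNA here. Regulatory T-like cells, which restrain immune responses, were 8.92% of CD4 T-like cells in PP with MC and 15.4%, 13.0% and 11.5% with Allobaculum, A. muciniphila and both. The Foxp3 level of CD4 T-like cells in PP did not follow this order, at 74.5 CPM with MC and 65.9, 90.6 and 49.8 CPM with the additions. In MLN they ranged from 10.6% to 12.7%, and every log2 ratio to MC there had an interval that includes 0. After thinning, Foxp3 was seen in 3.61% of CD4 T-like cells of PP with MC and in 6.58%, 7.09% and 4.51% with the additions. These are above MC, but their intervals overlap that of MC. Per library it was seen in 3.61% to 7.09% of CD4 T-like cells and in at most 0.256% of B-like cells. The median depths of these classes were 1292 to 2135 and 1262 to 1911.5 UMIs.

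Plasma cell-like barcodes, the antibody secretors, were 4.08% of the B lineage and plasma cells in MLN with Allobaculum and 2.48% with A. muciniphila, against 0.878% with MC and 0.872% with both. In the Allobaculum MLN library, 92 of the 116 such barcodes carried the same pair of V genes, Ighv5-6 and Igkv14-111, together with Ighg1, and 86 of the 116 had under 500 genes. Counting each pair of V genes once per library gave a log2 ratio of -0.13 (-1.02 to 0.76) in place of 2.22 (1.56 to 2.87) for Allobaculum, and of 0.36 (-0.53 to 1.25) for A. muciniphila, whose interval was 0.78 to 2.22 before. In PP the plasma cell-like share lay between 1.25% and 1.53%. Ighg1, the IgG1 heavy chain, was the leading isotype in 106 of these 116 MLN barcodes and in 8 of 22 with MC.

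**Figure D1:**
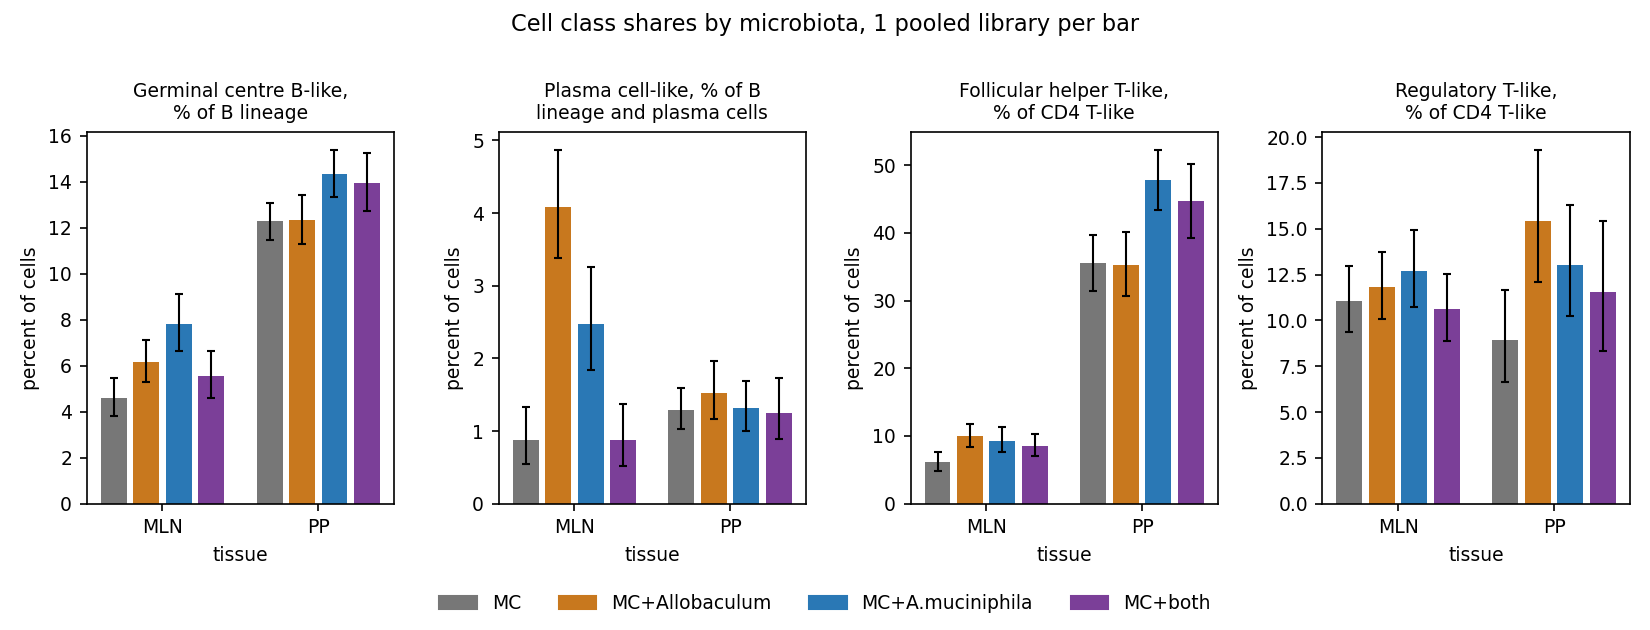
Share of cells (percent, vertical axis) for 4 classes in each of the 8 libraries, with exact 95% intervals for counting error. In MLN the germinal centre B-like share is 4.59% with MC, 7.82% with A. muciniphila and 5.57% with both species.

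The title also asks whether effects of the 2 species add up. In MLN, MC+both had fewer germinal centre B-like, follicular helper T-like and plasma cell-like cells than the single additions predict when their log2 ratios are summed. The germinal centre share would be 10.5% if additive and was 5.57%, a log2 departure of -0.92 (-1.39 to -0.44). The follicular helper share would be 15.3% and was 8.54% (-0.84, -1.39 to -0.28), and the plasma cell-like share would be 11.5% and was 0.872% (-3.72, -4.74 to -2.71). The regulatory share departed by -0.36 (-0.82 to 0.10) in MLN and by -0.97 (-1.71 to -0.23) in PP, while the PP departures were -0.05 for germinal centre, -0.09 for follicular helper and -0.30 for plasma cell-like cells. The differences between the tissues were not tested. The germinal centre and follicular helper departures became -0.32 (-0.79 to 0.16) and 0.13 (-0.43 to 0.69) once barcodes with T and B transcripts, 20.2% of the A. muciniphila MLN library, were counted in the denominators. The same step turned the regulatory departure of MLN to 0.61 (0.15 to 1.08), since most of these barcodes lie in the A. muciniphila library and lower its shares whatever their nature. At a Leiden resolution of 0.6, added after seeing the data, the follicular helper departure of MLN was -0.44 (-0.97 to 0.10) and the regulatory one 0.0714 (-0.38 to 0.52) in MLN and -0.58 (-1.31 to 0.15) in PP. The regulatory departure of PP was -0.67 (-1.44 to 0.10) with the tissues clustered apart, -1.52 (-2.87 to -0.17) with thinned Foxp3 UMIs and -1.06 (-1.80 to -0.31) with mixed barcodes in the denominator. The plasma cell-like departure became -0.57 (-1.91 to 0.77) with each pair of V genes counted once, an interval that includes 0. Under the stricter quality limits it became -1.19.

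Gene levels of the whole CD4 T-like and B-like classes departed from additivity in both directions. These classes hold the follicular helper and germinal centre clusters, so the levels are not independent of the shares above. Pdcd1, Il21, Cxcr5 and Fas are among the markers that named those clusters. The mixed barcodes are left out of these levels too. Levels sum UMIs, so deeper cells weigh more. The median depth of germinal centre B-like cells of MLN ran from 2991 UMIs with A. muciniphila to 8736 with both. In CD4 T-like cells of MLN the departure was -1.49 (-2.03 to -0.94) for Pdcd1, the inhibitory receptor PD-1, and -1.95 (-3.34 to -0.57) for Il21, the cytokine of follicular helper T cells. Il21 there had 8 UMIs with MC, at 4.14 CPM against 12.4, 13.1 and 10.1 CPM with the additions. Its departure thus rests on the low MC value. Pdcd1 also departed in PP, by -1.21 (-1.64 to -0.78), whereas the PP departure of Il21 was 0.02. Foxp3, the lineage factor of regulatory T cells, departed by -0.51 (-0.95 to -0.06) in MLN. Cxcr5, the receptor that leads cells to follicles, departed there by -0.93 (-1.76 to -0.09). Departures of genes were not recomputed with TMM factors. In CD4 T-like cells of MLN those factors shift the ratios to MC by -0.10, -0.07 and 0.11 for Allobaculum, A. muciniphila and both. Each of these shifts raises a departure, so the Foxp3 and Cxcr5 intervals would then include 0. B-like ratios of MLN shift likewise, by -0.09, -0.07 and 0.11. In B-like cells of MLN the departure was -0.72 (-0.89 to -0.55) for the proliferation marker Mki67 and -0.91 (-1.49 to -0.32) for Fas. Bcl6 in B-like cells departed by 0.01 in MLN. Igha in MLN departed upward, by 2.76 (1.94 to 3.57), with 505 of the 558 UMIs of the library with both species in 1 barcode, while Ighg1 departed by -1.32 and Ighg2b by -1.88. In the A. muciniphila MLN library 1 barcode held 434 of the 865 Ighg1 UMIs, and 1 held 48 of the 170 Ighg2b UMIs. In PP, the B-like departures of Mki67 and Fas were -0.04 each, those of Ighm and Ighd 0.38 and 0.31.

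**Figure D2:**
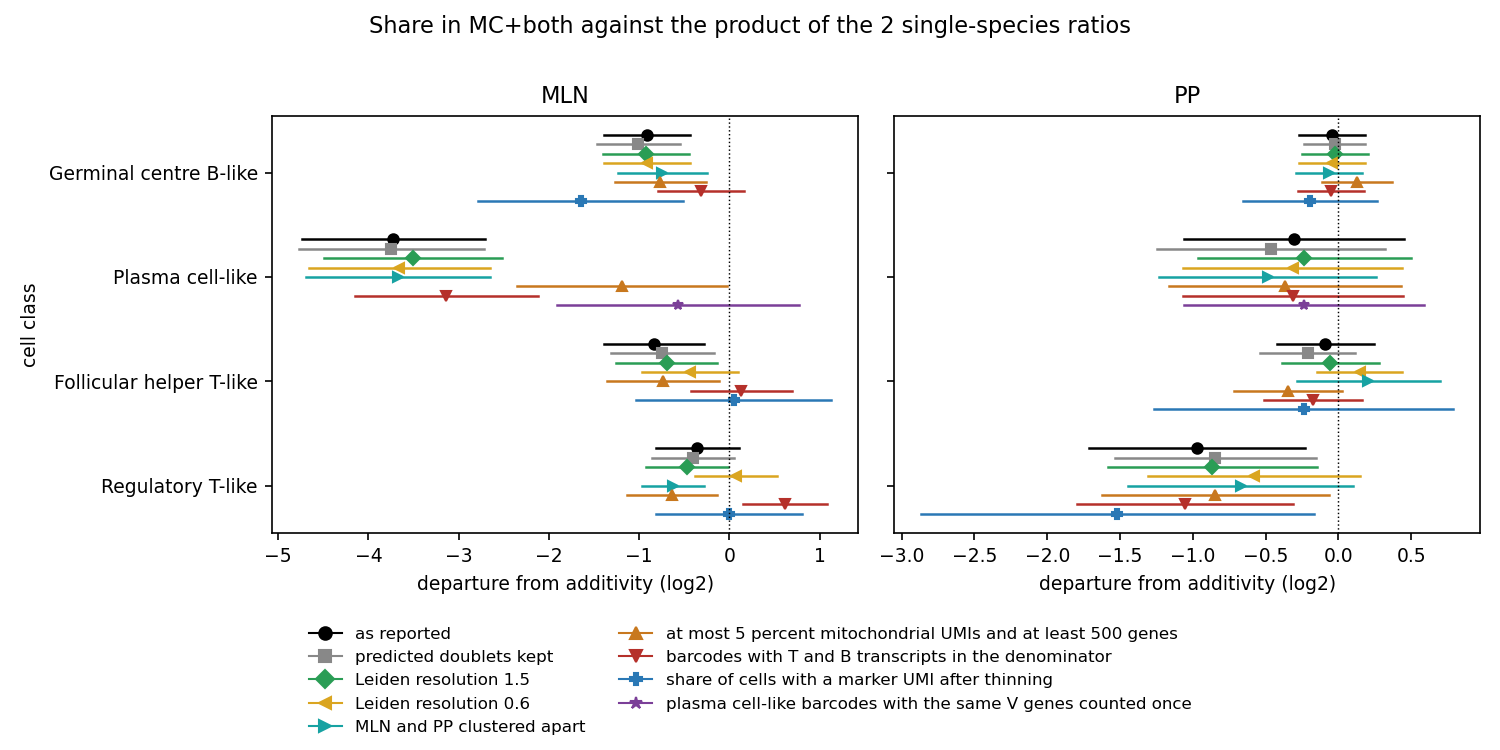
Departure from additivity on the log2 scale (horizontal axis) of 4 shares in MLN and PP, as reported and under each alternative, with 95% intervals for counting error. As reported, the germinal centre, follicular helper and plasma cell-like shares of MLN lie at -0.92, -0.84 and -3.72.

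With Allobaculum added to MC, the CD4 T-like cells carried more transcripts of Cxcr3, the chemokine receptor of Th1 cells, in both tissues. Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269) was 31.4 CPM in MLN against 10.3 with MC and 96.4 against 35.2 in PP, log2 ratios of 1.60 and 1.45. Tnfsf11, which encodes the cytokine RANKL, had log2 ratios of 0.80 in MLN and 1.74 in PP, and Asb2 had 1.34 and 0.87. The other genes named as higher were S100a6 (0.95 and 0.85), Cd1d1 (0.87 and 1.09) and Bscl2 (0.81 and 0.82). The lower genes moved less and were Tmsb10, Hspe1, Nop10, Dynll1 and Atp5e, from -0.24 to -0.37 in MLN and from -0.23 to -0.52 in PP. With A. muciniphila the CD4 T-like genes named as higher were Cxcr3 (1.28 and 0.95), Acot7 (1.18 and 1.13), Ehbp1l1 (1.02 and 1.06), Fam129a (0.93 and 1.25), Slc45a4 (0.86 and 0.93) and Fbxw4 (0.93 and 0.86). Those named as lower, Cuta, Higd1a, Pfdn2, Crip1, Dynll1 and Emp3, ran from -0.34 to -0.39 in MLN and from -0.55 to -0.80 in PP.

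With both species, CD4 T-like cells had more Asb2 (0.79 and 0.75), Fbxw4 (0.69 and 1.24), Nav2 (0.79 and 0.63), Taf1b (0.60 and 0.72) and Mrto4 (0.58 and 0.87) than with MC. Olfr77, annotated as an olfactory receptor gene, had log2 ratios of 1.19 and 2.29. Stk11, a kinase that activates AMPK, was named as lower (-0.53 and -0.85), with Rcor1, Usp7, Man1a2 and BC005537 from -0.38 to -0.52 in MLN and from -0.66 to -0.80 in PP. Against Allobaculum alone, MC+both had less Tnfsf11 (-1.27 and -0.92), Cxcr3 (-1.14 and -0.66), N4bp1 (-0.67 and -0.70) and Igtp (-0.75 and -1.29), an interferon-induced GTPase. It had more Olfr77 (1.01 and 3.63), Pfdn2 (0.48 and 0.77), Banf1 (0.63 and 0.48) and Ly6a (0.38 and 0.64). Against A. muciniphila alone it had less Prag1 (-1.03 and -0.76), Zkscan17 (-0.77 in MLN), Gbp9 (-0.76 and -0.73) and Odc1 (-0.82 and -0.75), the rate-limiting enzyme of polyamine synthesis. Higher there were Pfdn2, Banf1, Hint1 and Emp3, from 0.38 to 0.62 in MLN and from 0.41 to 0.60 in PP.

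Among the always-named CD4 genes, Pdcd1 was higher than with MC by 1.11 in MLN and 0.46 in PP with Allobaculum, and by 0.48 and 0.91 with A. muciniphila, but by 0.11 and 0.16 with both. Il21 in MLN was 4.14 CPM with MC and 12.4, 13.1 and 10.1 CPM with the additions. In PP it was 46.1, 40.2, 95.6 and 84.8 CPM. Bcl6, the lineage factor of follicular helper T cells, had MLN log2 ratios of 0.56, 0.09 and 0.21 and PP ratios of -0.29, 0.59 and 0.30. Gata3, the Th2 factor, lay between 44.9 and 77.4 CPM, and Foxp3 between 49.8 and 90.6 CPM. The depth was too low to compare lineage cytokines: Il17a had 0 UMIs in all 8 libraries, and per library Ifng had at most 4, Il10 at most 7 and Tbx21 at most 17.

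The follicular helper T program was higher in MLN with each single addition. With Allobaculum 15 of its 16 members were higher in MLN (median 0.54, percentile 100), among them Maf (0.68), but 4 of 16 in PP (-0.14, percentile 1.30). With A. muciniphila 14 of 16 were higher in MLN (0.33) and 15 of 16 in PP (0.45), among them the costimulatory receptor Icos (0.52 and 0.65). With both, 12 of 16 were higher in each tissue (0.19 and 0.34). The CD4 T-like class includes the follicular helper cluster, named with markers of this list, so these medians include differences in its share. The MLN share ratios were smaller with thinned Bcl6 UMIs, and that of A. muciniphila turned with mixed barcodes counted. The Th1 program had PP medians of 0.94, 0.83 and 0.71 and MLN medians of 0.03, 0.22 and -0.38. All PP medians share 1 MC library, against which erythroid markers of these cells lay at -4.53, -4.70 and -4.45. The regulatory T program had medians of 0.17, 0.28 and -0.06 in MLN and 0.28, 0.60 and 0.30 in PP, with 16 of 16 members higher in PP with A. muciniphila. Proliferation genes in MLN had medians of 0.38, 0.38 and 0.31, and glycolysis genes 0.30, 0.24 and -0.03. The Th17 program had medians from 0.14 to 0.42, the Th2 program from -0.20 to 0.34, the naive T program from -0.14 to 0.03 and gut homing genes from -0.04 to 0.34. A scaling by TMM shifts the median log2 ratio of the CD4 T-like and B-like classes by -0.14 to 0.21, depending on the pair of libraries.

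**Figure D3:**
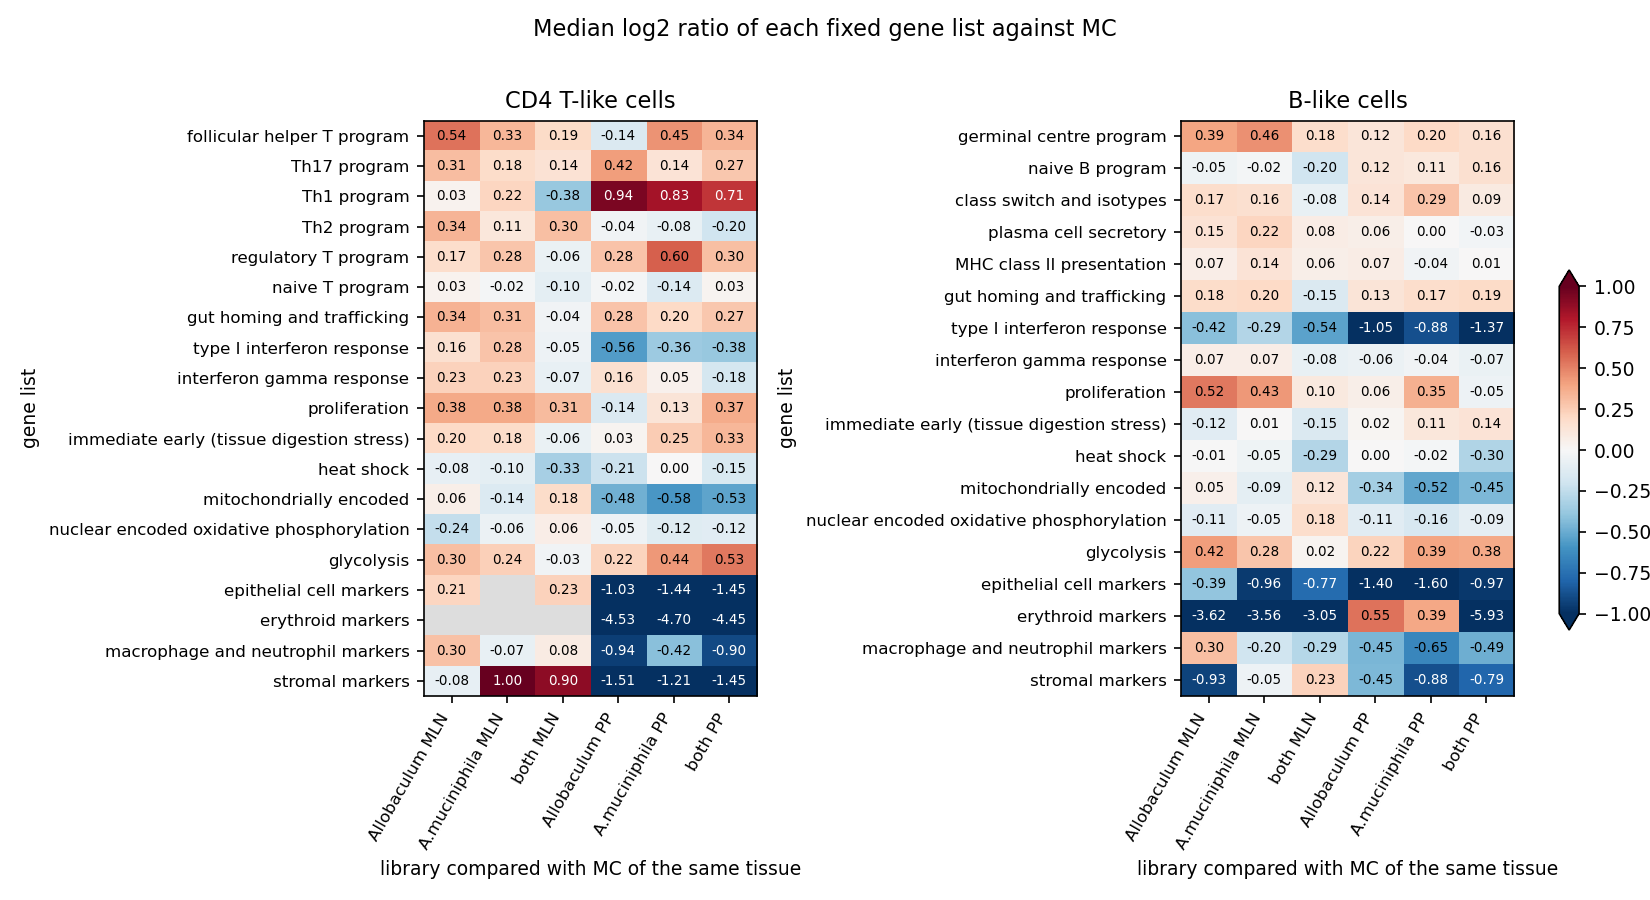
Median log2 ratio to MC (number and colour) of the fixed gene lists in CD4 T-like and B-like cells, by added species and tissue. The follicular helper T program is at 0.54 in MLN with Allobaculum, and the type I interferon list of B-like cells at -1.37 in PP with both species.

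In B-like cells the interferon-induced genes and the inducible heat shock genes set the MC libraries apart from all 3 others. The type I interferon list, genes of the antiviral response, had medians of -0.42, -0.29 and -0.54 in MLN and -1.05, -0.88 and -1.37 in PP with Allobaculum, A. muciniphila and both, at percentiles of at most 0.01. Some of the B-like cells formed a cluster of their own marked by these genes, so the medians need not hold for most B-like cells. In PP 16, 15 and 16 of its 16 members were lower, among them Ifit3 (-2.81, -2.11 and -4.94) and Usp18 (-1.46, -1.44 and -1.65). The CD4 T-like cells of PP had medians of -0.56, -0.36 and -0.38 for this list, and those of MLN 0.16, 0.28 and -0.05. Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), the inducible chaperone HSP70, was 51.5 CPM in MLN and 19.8 in PP with MC and at most 3.23 in the other libraries. With both species in PP it had 0 UMIs, at least 34.7-fold lower. Hspa1b had MLN log2 ratios of -5.31, -2.62 and -5.31. Both were high across the whole MC libraries and not in B-like cells alone, Hspa1a at 40.6 CPM in MLN and 20.5 in PP against at most 6.30 elsewhere, and Hspa1b at 75.5 and 47.0 against at most 14.2. The whole heat shock list had medians from -0.30 to 0.00 in B-like cells and from -0.33 to 0.00 in CD4 T-like cells. Markers of other cells and of RNA quality differed as well. Erythroid markers in B-like cells had medians of -3.62, -3.56 and -3.05 in MLN and of 0.55, 0.39 and -5.93 in PP. Epithelial markers of PP in B-like cells had medians of -1.40, -1.60 and -0.97 and mitochondrially encoded genes of -0.34, -0.52 and -0.45, and mitochondrially encoded genes of CD4 T-like cells had -0.48, -0.58 and -0.53.

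Among the other B-like genes, Ighg3, an IgG heavy chain, was higher with Allobaculum (1.07 in MLN and 1.24 in PP) and with A. muciniphila (1.10 and 0.96). With Allobaculum, Tbxa2r (0.97 and 0.92), Pars2 (1.77 and 0.86), St7 (0.94 and 0.72), Ahcy (0.90 and 0.71) and Jade3 (1.14 and 0.70) followed. Il5ra, the interleukin 5 receptor, was lower (-1.93 and -1.10), as were the interferon-induced genes Ifit2 (-0.75 and -1.29), Isg15 (-0.73 and -1.27) and Slfn5 (-0.72 and -1.31). With A. muciniphila, Socs3, an inhibitor of cytokine signalling (1.04 and 1.04), Ddit4 (1.33 and 0.96), Ighg2b (1.15 in PP), Hs3st1 (0.84 and 0.80) and Scamp4 (0.79 and 0.88) were higher. Ly6k (-1.46 and -1.02), Prag1 (-1.73 and -0.75) and Churc1 (-0.64 and -0.54) were lower. The MLN values of Jade3 and of Ighg2b turned to -0.27 and -0.17 after thinning, and 48 of the 170 Ighg2b UMIs in MLN came from 1 barcode. With both, Ptpn22, a phosphatase that limits receptor signalling (0.68 and 1.31), Tuba1a (0.75 and 0.82), Fkbp5 (0.73 and 0.96), Gkap1 (0.83 and 0.77), Hs3st1 (0.60 and 0.59) and Olfr77 (1.24 and 2.80) were higher. Il5ra (-2.16 and -1.67), Ifit2 (-1.48 and -1.16) and Cmpk2 (-0.82 and -0.80) were lower.

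Against Allobaculum alone, B-like cells with both species had less Tmem176a (-1.66 and -0.89), Tmem176b (-0.72 and -1.32), Abcd3 (-0.96 and -0.78) and Oip5 (-0.86 and -0.78). They had more Olfr77 (1.07 and 2.56), Eps8l1 (0.59 and 0.68), Mid1 (0.51 and 0.63) and Erh (1.03 and 0.27). Against A. muciniphila alone they had less Hspa1b (-2.69 and -1.65), Clu (-1.25 and -0.81), Scly (-0.85 and -0.78) and Cep55 (-0.73 and -0.85), and more Gkap1 (1.04 and 0.77), Cmc1 (0.87 and 0.64), Mid1 (0.69 and 0.59) and Cdk5rap1 (0.51 and 0.61). The MLN value of Oip5 turned to 0.32 after thinning.

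The germinal centre program of B-like cells was higher in MLN with each addition, in 14, 13 and 10 of its 15 members (medians 0.39, 0.46 and 0.18, percentiles of at least 99.8). Examples are Gcsam (0.73 and 0.87 with the single additions) and Rgs13 (0.65, 0.77 and 0.70), whereas Bcl6 was lower (-0.19, -0.31 and -0.48). The B-like class includes the germinal centre cluster, named with markers of this list, so the medians include the difference in its share. For A. muciniphila that difference depended on how mixed barcodes are counted. Levels also sum UMIs over the class, so deeper cells weigh more. Germinal centre B-like cells of MLN had median depths of 3737, 6073, 2991 and 8736 UMIs with MC, Allobaculum, A. muciniphila and both. The levels of MLN below carry this weighting too. In PP the medians of the germinal centre program were 0.12, 0.20 and 0.16. Proliferation genes in MLN had medians of 0.52, 0.43 and 0.10 and in PP of 0.06, 0.35 and -0.05. They were lower with both species than with A. muciniphila alone in MLN (-0.33) and in PP (-0.19). Mki67 in MLN was 257, 317, 290 and 218 CPM with MC, Allobaculum, A. muciniphila and both. Medians of the remaining B cell lists ran from -0.08 to 0.29 for class switch, from -0.03 to 0.22 for plasma cell secretory genes, from -0.04 to 0.14 for MHC class II, from -0.20 to 0.16 for the naive B program and from -0.15 to 0.20 for gut homing. Interferon gamma genes ran from -0.08 to 0.07, immediate early genes from -0.15 to 0.14, oxidative phosphorylation from -0.16 to 0.18 and glycolysis from 0.02 to 0.42.

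Immunoglobulin levels of B-like cells often rested on single barcodes. Igha, the IgA heavy chain, was 115 CPM in MLN with both against 7.02 with MC, but 505 of its 558 UMIs came from 1 barcode, and the level without it was 11.02 CPM. Ighg1 in MLN was 117, 136, 254 and 118 CPM, with 434 of the 865 UMIs of the A. muciniphila library in 1 barcode. Jchain, which joins secreted IgA and IgM, was 130, 180, 333 and 280 CPM in MLN, and 204 and 182 CPM in the last pair of libraries without their leading barcode. Ighm and Ighd, the isotypes of naive B cells, were lower in PP with every addition, at log2 ratios of -0.36, -0.41 and -0.39 for Ighm and -0.30, -0.42 and -0.41 for Ighd. Ighg2c had at most 15 UMIs per library. In plasma cell-like barcodes, Igha had log2 ratios to MC of 1.11, 1.38 and 1.10 in PP and of -0.38, -2.03 and -0.71 in MLN. In each MLN library 1 barcode held over 50% of these UMIs, and without it the levels were 2206, 801, 367 and 1213 CPM with MC, Allobaculum, A. muciniphila and both.

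**Figure D4:**
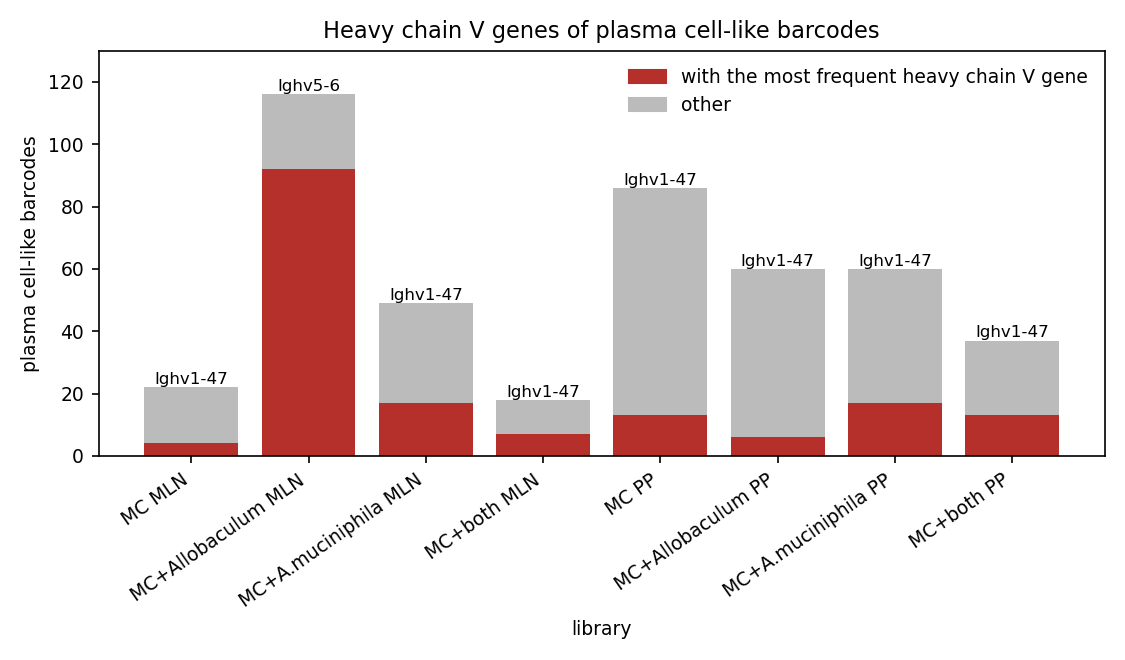
Plasma cell-like barcodes per library (count), split by whether they carry the library's leading heavy chain V gene. In the MLN library with Allobaculum 92 of 116 barcodes carry Ighv5-6.

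The second comparison, of PP with MLN across the 4 pools, describes how the tissues differ whatever the microbiota. B lineage cells made up 76.9% ± 2.76 (SD, n = 4) of the PP cells and 42.2% ± 6.25 of the MLN cells, and CD4 T-like cells 7.94% ± 1.23 and 21.4% ± 2.92. Germinal centre B-like cells were 13.2% ± 1.08 of the B lineage in PP and 6.04% ± 1.36 in MLN, higher in 4 of 4 pools by a mean of 7.20 percentage points. Follicular helper T-like cells were 40.8% ± 6.40 of CD4 T-like cells in PP and 8.49% ± 1.70 in MLN, higher in 4 of 4 pools by 32.3 points. CD8 T-like cells were 3.17% of PP cells and 17.1% of MLN cells, dendritic cell or macrophage-like cells 2.46% and 5.64%, and cytotoxic or gamma delta T-like cells 1.56% and 0.188%. For each of these shares the exact two-sided sign-flip permutation p was the smallest that 4 pairs allow, and 0.161 after adjustment over 18 shares. The regulatory T-like share differed by 0.678 points, higher in 3 of 4 pools (exact permutation p = 0.662 after adjustment), and by -0.298 without the Allobaculum pool. The plasma cell-like share of the B lineage differed by -0.731 points, higher in 2 of 4 pools (exact permutation p = 0.562 after adjustment), and by -0.123 without the Allobaculum pool. Epithelial-like cells were 3.84% of PP cells and 0.0046% of MLN cells, higher in 4 of 4 pools.

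Taken as a whole class, CD4 T-like cells of PP had much higher levels of the follicular helper program. The class includes the follicular helper cluster, which was named with markers of this list. That cluster was 40.8% of the class in PP and 8.49% in MLN, so the levels include this difference in share and are no independent evidence. All 16 tested members rose (median log2 fold change 2.05), with Asb2 outside the list at 3.00 (SE 0.137, adjusted p = 2.7e-10), Tox2 at 2.48, Cxcr5 at 2.32, Pdcd1 at 2.23, Bcl6 at 1.84 and Il21 at 2.61, each higher in 4 of 4 pools. Camera gave an adjusted p = 2.2e-79 for this list and an adjusted p = 0.0425 with an estimated correlation. Of the naive T program 11 of 12 members fell, among them Dapl1 (-1.24) and the exit receptor S1pr1 (-0.86), while Tcf7 was at 0.25 (adjusted p = 3.0e-17 for the list, adjusted p = 0.0425 with an estimated correlation). In the regulatory T program 7 of 14 rose, Tigit (2.42), Ikzf2 (1.16) and Ctla4 (0.75) among them (adjusted p = 8.5e-09, adjusted p = 0.0425 with an estimated correlation). Adjusted over the list alone, 8 were higher in PP and 2 higher in MLN. Tigit also marks the follicular helper cluster, which is larger in PP, while the regulatory T-like share was 12.2% in PP and 11.6% in MLN. The rise therefore need not lie in regulatory T-like cells. Foxp3 did not pass (-0.22, SE 0.141, adjusted p = 0.413, lower in 4 of 4 pools), nor did Gata3 (0.20, adjusted p = 0.487, higher in 3 of 4) or Tbx21 (0.44, adjusted p = 0.683, higher in 2 of 4). Ifng, Il10 and Il17a had too few counts to be tested.

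Of the Th17 program 6 of 8 tested members rose in PP, among them the aryl hydrocarbon receptor Ahr (1.58), Rora (1.45) and the receptor Ccr6 (1.18), with an adjusted p = 0.0634 with an estimated correlation. Of the Th1 program 4 of 7 rose, Cxcr3 (1.59) and Ccl5 (1.41) among them (adjusted p = 0.0911 with an estimated correlation), and of the Th2 program 2 of 6, Il4 (2.84) and Il9r (2.48) (adjusted p = 0.052 with an estimated correlation). Immediate early genes, which respond to stimulation and to tissue digestion, rose in 6 of 14 members, Fos (2.49) and Nr4a1 (1.67) among them (adjusted p = 0.0911 with an estimated correlation). Interferon gamma genes fell in 4 of 14 (adjusted p = 0.0911 with an estimated correlation). Gut homing genes went both ways, 5 up and 4 down of 12 (adjusted p = 0.149). Adjusted over the list alone, the Th17, Th1, Th2 and immediate early lists had 7, 4, 3 and 8 called members. Further genes named as higher were Sostdc1 (2.73), Nav2 (2.33), Cd160 (2.27), Anxa2 (2.09) and the enterocyte gene Fabp2, which had 0 UMIs in MLN. Lower were Ggt5, Tgtp2, St8sia6, Arsb, Cnn3, Sema4a, Galnt10, Cd55 and Dirc2, from -0.99 to -1.24. In all, edgeR with Benjamini-Hochberg adjustment called 855 of 9277 genes, 585 higher in PP and 270 higher in MLN. Of the 585, 29 were at least 10 times higher in epithelial-like cells, and 4 of 4 epithelial markers rose in PP (adjusted p = 2.2e-21, but adjusted p = 0.052 with an estimated correlation). With the follicular helper and regulatory T-like clusters left out, an alternative chosen after seeing the data, 28 genes were called, and Bcl6 was then at 0.07 and Nav2 at 0.42. Tgtp2 and Arsb were still called there, but Dapl1 (-0.25), Ggt5 (-0.33), Cnn3 (-0.33), Galnt10 (-0.25), Dirc2 (-0.25), St8sia6 (-0.19), Cd55 (-0.12) and Sema4a (-0.0639) were not, so values of all CD4 T-like cells include the difference in make-up. The count was 476 without the A. muciniphila pool and 568 without the Allobaculum pool.

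**Figure D5:**
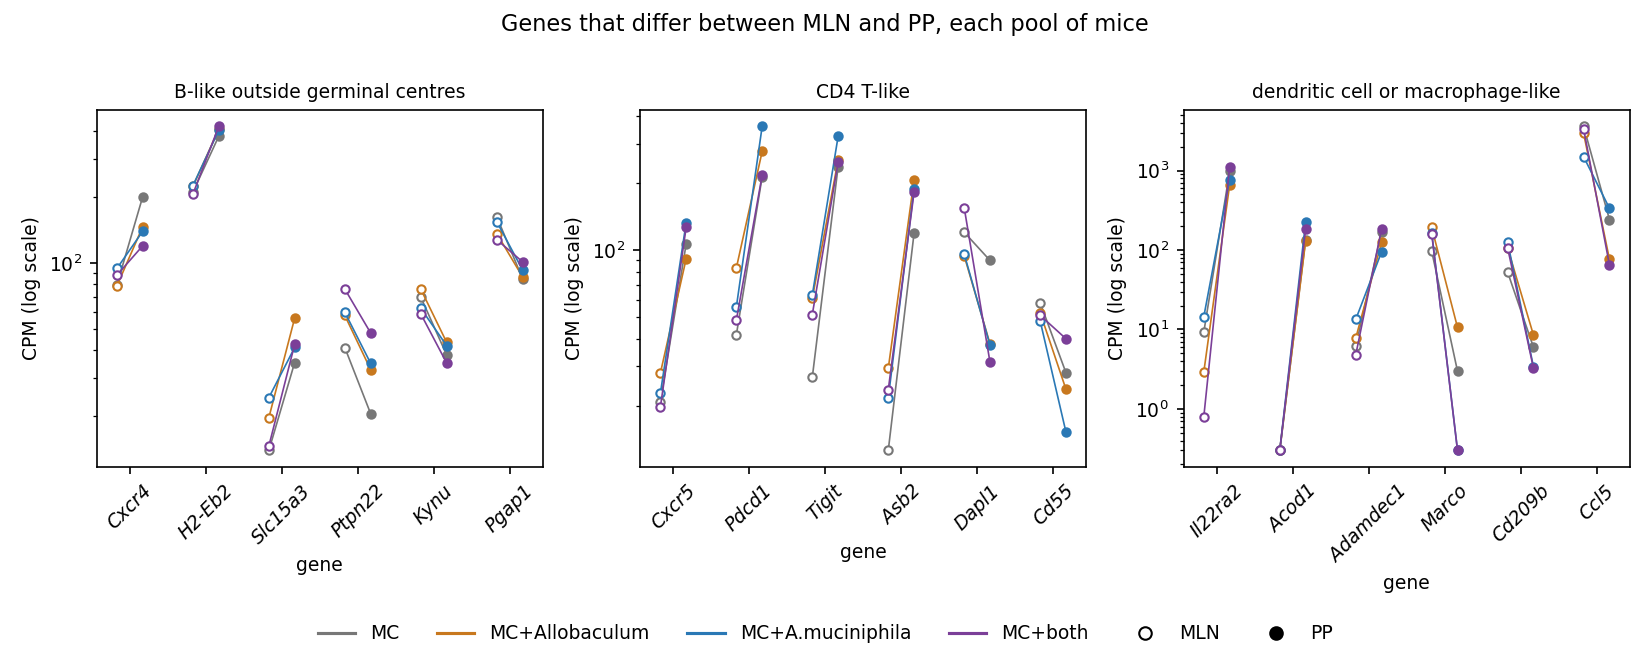
Level (CPM, log scale) of 6 named genes in each of 3 cell classes, with a line from MLN to PP for each of the 4 pools, and libraries at 0 drawn at the bottom. Asb2 in CD4 T-like cells has a log2 fold change of 3.00, and Ptpn22 in B-like cells outside germinal centres of -0.81.

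B-like cells outside germinal centres differed less. In PP they had more Igha (1.69, SE 0.142, adjusted p = 7.9e-05, 4 of 4 pools), H2-Eb2 (0.90), the chemokine receptor Cxcr4 (0.82), Slc15a3 (1.28), Tle3 (1.03), Fmnl3 (0.93), Skil (0.91), Cpm (0.82) and Syngr2 (0.80). In MLN they had more Ptpn22 (-0.81, adjusted p = 0.000716, 4 of 4 pools), Kynu (-0.75) and Cpt1a (-0.57), the entry enzyme of mitochondrial fatty acid oxidation. Pgap1, Gucd1, Clec2d, Trim34a, Fchsd2 and AC113595.1 ran from -0.55 to -0.67. Clec2d, Cpt1a, Trim34a and Fchsd2 were called in 3 and AC113595.1 in 2 of the 4 fits without a pool. Bcl6 was lower in PP (-0.44, adjusted p = 0.0296, 4 of 4 pools), a call that held in 1 of the 4 fits without a pool. Ighg2b (0.97, adjusted p = 0.111), Ighg3 (1.01), Jchain (0.77), Mki67 (0.60), Ighg1 (-0.37), Fas (-0.38), Ighm (0.07) and Ighd (0.01) did not pass, and Ighg2c was not tested. Over all B-like cells, germinal centre ones included, 1 barcode held 659 of the 983 Igha UMIs of PP with Allobaculum. In MLN with both species 1 barcode held 505 of 558. Whether these barcodes lie outside germinal centres was not looked at. In all 304 of 10278 genes were called, 203 higher in PP and 101 higher in MLN, and the count was 154 without the Allobaculum pool and 146 without the A. muciniphila pool. Of the 203, 64 were at least 10 times higher in epithelial-like cells, such as the Paneth cell defensin Defa24, at 0 UMIs in MLN and a mean of 120 CPM ± 122 (SD, n = 4) in PP.

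By list, the class switch genes rose in 2 of 12 tested members, Igha and Tgfbr1 (0.55), a receptor of TGF-beta, and in 5 of 12 adjusted over the list alone (adjusted p = 2.9e-05, but adjusted p = 0.134 with an estimated correlation). MHC class II rose in 2 of 13, Cd83 (0.61) and Ciita (0.35) (adjusted p = 0.276 with an estimated correlation), and glycolysis in 3 of 12, Gapdh, Eno1 and Tpi1 (adjusted p = 0.139 with an estimated correlation). Interferon gamma genes fell in 3 of 13, Gbp2 (-1.09), Gbp3 (-0.92) and Irf1 (-0.45) (adjusted p = 0.134 with an estimated correlation). In the naive B program 2 members rose and 3 fell of 13 (adjusted p = 0.208 with an estimated correlation). Markers of other cells moved beside these lists: 9 of 10 epithelial and 5 of 5 erythroid markers rose in PP (adjusted p = 0.102 and adjusted p = 0.139 with an estimated correlation). No list of this class kept its call with an estimated correlation.

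Germinal centre B-like cells of PP had more Ighg2b (1.87, SE 0.326, adjusted p = 0.0194, 4 of 4 pools), Osbpl3 (1.13) and the signalling regulator Rgs1 (1.12). Those of MLN had more Slpi, a protease inhibitor (-3.17, SE 0.405, adjusted p = 0.00327, 4 of 4 pools), S100a10 (-1.45), Mndal (-1.31) and Klf2 (-1.30), a factor that maintains the egress receptor S1pr1. Slpi also marks the plasma cell-like cluster, at 7231 CPM in its MLN barcodes. The plasma cell secretory list had 0 called members of 12 in germinal centre B-like cells but was higher in MLN (adjusted p = 0.0041, and adjusted p = 0.485 with an estimated correlation). Ighg2b, Osbpl3 and Rgs1 were called in 3 of the 4 fits without a pool. Over all B-like cells of PP, 1 barcode held 653 of 1052 Ighg2b UMIs with both species, 273 of 868 with MC and 160 of 492 with Allobaculum. With A. muciniphila it held under 25%. The split of these barcodes between germinal centre and other B-like cells was not looked at. EdgeR called 78 of 9397 genes, 18 higher in PP and 60 higher in MLN. Klf2 was among the naive B members that fell, 2 of 13 (adjusted p = 0.107 with an estimated correlation). The germinal centre program and the interferon gamma list had 0 called members of 15 and 12, although camera gave an adjusted p = 2.6e-05 and an adjusted p = 1.5e-06 (adjusted p = 0.107 with an estimated correlation for both).

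The dendritic cell or macrophage-like class of PP had far more Il22ra2, the decoy receptor of interleukin 22 (7.08, SE 0.313, adjusted p = 3.7e-12, 4 of 4 pools), and more Adamdec1 (4.19), Hic1 (3.87) and Ccr1 (3.46). Acod1, which makes itaconate, had 0 UMIs in MLN and a mean of 167 CPM ± 44.3 (SD, n = 4) in PP. That of MLN had more Marco (-5.15, SE 0.353, adjusted p = 2.4e-09, 4 of 4 pools), Cd209b (-3.92) and Siglec1 (-3.08), receptors of lymph node macrophages, and more Ccl5 (-4.09) and Synpo2 (-3.12). Interferon gamma genes fell in 8 of 13 members, Gbp4 (-1.52) and Irf1 (-1.32) among them (adjusted p = 0.0593 with an estimated correlation), while glycolysis genes rose in 7 of 12, Hk2 (2.11) among them (adjusted p = 0.0694 with an estimated correlation). Macrophage markers rose in 6 of 8, with C1qa at 1.62 and Lyz2 at 1.83 (adjusted p = 0.112 with an estimated correlation), and epithelial markers in 2 of 3 (adjusted p = 7.7e-09, but adjusted p = 0.0593 with an estimated correlation). EdgeR called 1038 of 9074 genes, 520 higher in PP and 518 higher in MLN. Restricted to the conventional dendritic cell cluster, an alternative chosen after seeing the data, it called 536, Il22ra2, Hic1, Ccr1, Marco and Ccl5 among them, and without the MC pool the whole class gave 652. The class joins clusters that the tissues hold in different proportions: the migratory dendritic cell cluster, marked by Ccl5, had 131 of 293 cells in MLN and 20 of 219 in PP with MC, and the macrophage cluster, marked by Lyz2, C1qa and Il22ra2, 72 and 118. Values of the whole class include this difference in make-up. In CD8 T-like cells 15 of 8566 genes were called, of which 10 of the 14 higher in PP were at least 10 times higher in epithelial-like cells. Dtx1, a regulator of Notch signalling (0.58, adjusted p = 0.0364, 4 of 4 pools), was higher in PP and Ly6c2, a marker of memory CD8 T cells, in MLN (-0.76, SE 0.146, adjusted p = 0.0106, 4 of 4 pools). Dtx1 was called in 0 and Ly6c2 in 1 of the 4 fits without a pool.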

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

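The UMI count of the mixed barcodes and their share in the library with both species were chosen as tests only after the result was seen, and the comparison with free RNA was set before.

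In the MLN library with A. muciniphila, 20.2% of the cells (1167 of 5783) carried both T and B cell transcripts, far from the 0.990% to 1.80% of the other MLN libraries. The tables argue against T and B cells caught in 1 droplet as the whole cause, because these barcodes had a median of 786 UMIs, 0.509 times the lower of the medians of B-like (1543) and CD4 T-like cells (1799). They argue as well against free RNA in the proportions of the whole library, since 3 of 9 marker lists lay beyond 2-fold of that library: plasma cell at a log2 ratio of -1.29 (-1.42 to -1.16), macrophage at -1.24 (-1.41 to -1.08) and fibroblast, on 10 UMIs, at -3.24 (-4.14 to -2.34). The other 6, B (-0.06) and T (0.23) among them, were within 2-fold. The MLN library with both species had 1.80% (87 of 4826), close to MC (94 of 5429), and the PP library with A. muciniphila had 9 of 5629. These values argue against a cell state that comes with A. muciniphila whatever the tissue and the other species. A state of MLN with A. muciniphila but without Allobaculum cannot be told apart from a fault of that only library. The mixed barcodes were left out of the B and T cell classes, so shares and gene levels of this library may rest on an uneven choice of cells.

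Besides this, other values of single libraries stood far from the rest of their tissue, 5 of 46 groups of 4 libraries in all, where chance alone flags about 1 in 20 groups. The MLN library with both species had a median of 2192 UMIs per cell, against 1482 to 1599 in the other MLN libraries. In the same library 3.19% of barcodes failed the quality limits, against 0.754% to 0.888%. Stromal or endothelial-like cells were 0.693% of the PP library with A. muciniphila, against 1.34% to 1.42% in the other PP libraries. Epithelial-like cells were 0.0184% of the MLN library with MC, which is 1 cell, against 0 in the other 3, a difference that says nothing by itself.

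In 17 of 122 contrasts the MLN and PP libraries went opposite ways, each beyond its counting interval, and the difference between the tissues was not tested in any of them. After thinning to 1000 UMIs 4 of them no longer did so: for both against Allobaculum, Cxcr5 (-0.22 in PP), Igha (0.0370 in PP) and Jchain (-0.0185 in MLN), and for both against A. muciniphila, Ighg2b (-0.41 in PP). In CD4 T-like cells this held for Cxcr5 with both species against Allobaculum (log2 ratio -0.73 in MLN and 0.53 in PP). In B-like cells Bcl6 was lower than with MC in MLN and higher in PP with Allobaculum (-0.19 and 0.24), A. muciniphila (-0.31 and 0.30) and both (-0.48 and 0.35). Mki67 was higher in MLN and lower in PP with Allobaculum (0.30 and -0.07). Ighg1 went opposite ways with Allobaculum (0.21 and -0.16) and A. muciniphila (1.11 and -0.47) against MC, and with both species against A. muciniphila (-1.11 and 0.31). Jchain did so with A. muciniphila (1.36 and -0.14) and both (1.11 and -0.24) against MC, and with both against Allobaculum (0.64 and -0.39). Ighg2b was lower in MLN and higher in PP with both species against MC (-1.11 and 1.39), Allobaculum (-0.88 and 1.43) and A. muciniphila (-2.11 and 0.24). Igha was higher in MLN and lower in PP with both species against Allobaculum (3.67 and -0.86) and A. muciniphila (3.12 and -0.18), and Ighg3 went the other way against A. muciniphila (-1.12 and 0.61). A single barcode held 505 of the 558 Igha UMIs of MLN with both species, 659 of the 983 Igha UMIs of PP with Allobaculum, 653 of the 1052 Ighg2b UMIs of PP with both, and 434 of the 865 Ighg1 UMIs of MLN with A. muciniphila.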

How the results depend on the processing

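Counting mixed barcodes in the denominator, counting each pair of V genes once, Leiden 0.6 and separate tissues for departures, other CD4 T-like cells alone and the conventional dendritic cell cluster alone were chosen only after the results were seen. Among planned and added alternatives, 244 of 275 share ratios, 56 of 63 departures of shares, 36 of 39 departures of genes and 3465 of 3854 gene ratios stayed the same. For ratios and log2 departures of shares this means within the counting interval of the reported value, which can be wide. For departures on the linear scale it means the same sign, and for shares also the same side of 0 for the interval. Departures of genes were recomputed on the linear scale only. Of 647 values of microbiota list medians, 546 stayed the same and 101 moved. Of the tested tissue genes 689 of 739 stayed the same, 45 fell short of the threshold and 5 came past it. Where a value changed, the cause was not tested unless stated. Log2 ratios are given as new value (value in the report).

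For shares, thinned marker UMIs gave, for germinal centre B-like cells of MLN, 0.81 (0.42) for Allobaculum, 1.26 (0.77) for A. muciniphila, -0.84 (-0.49) for both against A. muciniphila and a departure of -1.65 (-0.92). For follicular helper T-like cells of MLN they gave 0.0463 (0.71), 0.18 (0.61), 0.23 (-0.23) for both against Allobaculum and a departure of 0.0468 (-0.84). For PP they gave -0.48 (-0.01) for Allobaculum, -0.0834 (0.33) for both and -0.72 (-0.10) for both against A. muciniphila. Mixed barcodes in the denominator, which are mostly in 1 library, gave for MLN germinal centre cells 0.14 (0.77) for A. muciniphila, 0.13 (-0.49) for both against it and a departure of -0.32. They gave for follicular helper cells -0.40 (0.61), 0.89 (-0.12) and 0.13 (-0.84), and for regulatory cells -0.81 (0.20), 0.75 (-0.26) and 0.61 (-0.36). Limits of 5% mitochondrial UMIs and 500 genes gave for germinal centre cells of PP -0.19 (0.01), -0.0596 (0.22) and -0.12 (0.19), and for plasma cell-like cells of MLN 0.25 (2.22) for Allobaculum, -0.33 (-2.23) for both against it and a departure of -1.19 (-3.72). Each pair of V genes counted once gave for these -0.13 (2.22), 0.36 for A. muciniphila, -0.21 (-2.23) and -0.70 (-1.51) for both against each, and a departure of -0.57. Follicular helper ratios in PP became -0.27, 0.0558 and -0.0731 at a Leiden resolution of 0.6 and -0.39, 0.21 and 0.0289 with the tissues clustered apart, which resolved no such cluster in MLN and gave no value there. With doublets kept, the PP germinal centre ratio for both was 0.00808 (0.19), the unnamed B cluster differed by -2.59 points between PP and MLN (1.99), and plasma cell-like Ighm with Allobaculum in MLN was -0.0750 (0.18). At a resolution of 1.5 the unnamed cluster differed by -0.52 points.

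For genes in the tissue comparison, DESeq2 called 185 in B-like cells outside germinal centres, 408 in CD4 T-like cells and 439 in dendritic cell or macrophage-like cells. No filter on low counts gave 632, 307 in germinal centre cells and 41 in CD8 T-like cells. Leaving out 1 pool, which leaves fewer samples, gave 146 to 392 in B-like, 50 to 88 in germinal centre, 476 to 985 in CD4, 7 to 12 in CD8 and 652 to 925 in dendritic or macrophage-like cells. The germinal centre count was 50 without the Allobaculum pool, and the CD8 count 7 without the MC pool and 8 without either single addition. Other CD4 T-like cells alone gave 28, and the dendritic cell cluster alone 536. Without the block that pairs the tissues, CD8 T-like cells gave 5 genes, and the exact permutation p of the germinal centre, follicular helper and CD4 shares was 0.0286, the smallest possible, as was the paired p in the report. With an estimated correlation 0, 0, 3, 0 and 0 gene lists passed in B-like, germinal centre, CD4, CD8 and dendritic or macrophage-like cells, against 9, 9, 11, 5 and 5. The regulatory share differed by -0.298 points without the Allobaculum pool and by up to 1.62 (0.678), and the plasma cell-like share of all cells by -0.0166 without the MC pool, -0.00195 without the pool with both, and up to 0.461 (0.139).

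Depth limits single genes. After thinning to 1000 UMIs, CD4 T-like Banf1 and Cxcr5 for both against Allobaculum in PP became -0.12 and -0.22. In B-like cells Jade3 with Allobaculum in MLN became -0.27, Ighg2b with A. muciniphila in MLN -0.17 and Rgs13 in PP -0.000736. For both against Allobaculum, Oip5 in MLN became 0.32, Igha in PP 0.0370 and Jchain in MLN -0.0185, and against A. muciniphila Ighm in MLN 0.0106 and Ighg2b in PP -0.41. In plasma cell-like cells Ighg1 with Allobaculum in PP became -0.0187. With A. muciniphila, Ighm became -0.11 in MLN and 0.0460 in PP, Ighg1 0.00777 in PP and Ighg2b -1.79 in MLN. With both, Ighg1 became 0.13 in MLN and -0.13 in PP and Ighg2b 0.21 in PP, and Ighg1 0.51 in MLN against Allobaculum and -0.14 in PP against A. muciniphila. TMM factors turned H2-Eb1 with Allobaculum in PP to -0.0160, Ighm with both in MLN to 0.0103, Cd83 with both in PP to -0.0766, and for both in MLN Ighd against Allobaculum to 0.10 and Ighm against A. muciniphila to 0.0875. They turned plasma cell-like Ighm with Allobaculum in MLN to -0.0394. Totals without immunoglobulin, mitochondrial and ribosomal protein genes gave -0.00738 for that Cd83, 0.0159 for that Ighd, 0.0128 for that Ighm against A. muciniphila and -0.11 for the plasma cell-like Ighm.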

Other observations

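The tests of V gene pairs, of thinned markers, of the mixed barcodes in the denominator and of other splits of the libraries were chosen only after the results were seen, and the tests of related barcodes and of free plasma cell RNA before.

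Lists that the report leaves aside gave these medians against MC, in the order Allobaculum, A. muciniphila and both. In CD4 T-like cells, interferon gamma genes had 0.23, 0.23 and -0.07 in MLN and 0.16, 0.05 and -0.18 in PP. Immediate early genes, which respond to stimulation, had 0.20, 0.18 and -0.06 in MLN and 0.03, 0.25 and 0.33 in PP, where Nr4a1, an early gene of T cell receptor signalling, was at 1.85 and 1.82 with A. muciniphila and both. Oxidative phosphorylation genes had -0.24, -0.06 and 0.06 in MLN and -0.05, -0.12 and -0.12 in PP. Of markers of other cells in PP, erythroid ones had -4.53, -4.70 and -4.45, macrophage or neutrophil ones -0.94, -0.42 and -0.90, and stromal ones -1.51, -1.21 and -1.45. Olfr77 was seen across whole libraries, at 90.3, 101, 30.6 and 215 CPM in MLN and 12.8, 13.9, 84.9 and 83.0 CPM in PP with MC, Allobaculum, A. muciniphila and both.

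Plasma cell-like barcodes were 116 in the MLN library with Allobaculum, and 92 of them shared Ighv5-6, Igkv14-111 and Ighg1. Counting each pair of V genes once took the log2 ratio to MC to -0.13 (-1.02 to 0.76), so repeated barcodes of 1 chain pair may account for the higher share. The tables argue against 1 barcode read as many related ones, since the median distance to the nearest other barcode was 7 bases. They argue against free plasma cell RNA in all droplets too, as 0.0885% of T-like cells had a UMI of Ighv5-6. An expanded clone and fragments of 1 or a few cells stay open, and no biological explanation was tested.

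The germinal centre and follicular helper departures from additivity in MLN could come from depth or from the mixed barcodes. They also rest on the 1 MC library of MLN, since a low MC share alone makes a departure negative. That library stood apart in Hspa1a, at 40.6 CPM against at most 6.30 in the other MLN libraries. What part it played in the departures was not tested. Depth is argued against for germinal centre B-like cells, since the share with a marker UMI after thinning departed by -1.65 (-2.78 to -0.51), but it stays open for follicular helper T-like cells, where Bcl6 gave 0.0468 (-1.03 to 1.13). With the mixed barcodes in the denominators the departures were -0.32 (-0.79 to 0.16) and 0.13 (-0.43 to 0.69). This decides nothing, because the barcodes were added to no numerator and most lie in the A. muciniphila library, which raises the MLN departure whatever their nature, and the same step pushed the regulatory share to 0.61 (0.15 to 1.08); a part played by these barcodes stays open. An interaction of the 2 species stays open, with 1 library per microbiota and tissue.

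The 8 splits that keep the pools paired are too few for a share under 0.05. The real split called 304, 78, 855, 15 and 1038 genes in B-like, germinal centre, CD4, CD8 and dendritic or macrophage-like cells, and the highest other split 0, 6, 0, 5 and 0. Without the block, the real split called 269, 65, 889 and 952 genes in B-like, germinal centre, CD4 and dendritic or macrophage-like cells. No other of the 35 splits called as many, and the highest others gave 1, 1, 0 and 1. This argues against chance for the counts without the block only, because these splits ignore the pairing of the tissues. For the paired counts, on which the report rests, chance stays open. In CD8 T-like cells 2 of the 35 splits gave as many as the 5 of the real one, so chance cannot be excluded.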
